A study of Homo sapiens with 12 samples.

How the data were processed

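Total RNA of 2 glioblastoma cell lines was sequenced after transfection with XRN2 siRNA, a control siRNA or no siRNA, 12 libraries in all. Per the labels' protocols, RNA was taken 72 hours after reverse transfection and extracted with a column kit, libraries were made with the Illumina TruSeq RNA v2 kit and the sequencer was a MiSeq. That kit is known to select polyadenylated RNA and to keep no strand, so a change in RNA without a poly(A) tail is largely out of reach and overlapping genes share reads. Groups and replicate numbers were taken from the sample titles. The siRNA sequences are not given in the sources used here.

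For each library the authors deposited a table of genes, 58174 in number. Per the file headers, the deposited read counts are whole numbers of total and unique exon, exon-exon and intron reads per gene, beside the gene's position and exon length. Deposited TPM and RPKM values stand in the same tables, per the file headers; they were used here only to recover the number of mapped reads behind RPKM. In all 12 libraries total gene reads equalled total exon plus total intron reads for every gene. The submitters' processing notes name GRCh37 and hg19, but of 57836 gene identifiers shared with GENCODE release 29, 56000 (96.8%) had the same chromosome, start, end and strand there, so the coordinates in the files are those of GRCh38. The aligner and the counting program are not given in the sources used here. How reads with several matches were shared is not stated either, so genes with near-identical copies are uncertain.

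The total exon read counts as deposited were tested. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14232; 34683 genes had no read in any library. Counts were scaled by trimmed mean of M-values (TMM; factors 0.927 to 1.13). One mean per group was fitted to all 12 libraries with 6 residual degrees of freedom in edgeR 4.0.16, with robust quasi-likelihood dispersions, and contrasts were tested by the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. This pools the spread of all groups, since groups of 2 alone leave little to estimate it from. The contrasts were XRN2 siRNA against control siRNA in each line, their mean, their difference, control siRNA against mock in each line, and LN229 against U251 in mock. CPM values are TMM-scaled, and errors are SD over the 2 libraries of a group or SE of a fitted log2 fold change.

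The comparisons, the alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. The lists cover termination and 3′ end processing, snoRNA hosts, ribosome biogenesis, ribosomal proteins, histones, the transition between epithelial and mesenchymal states, matrix proteases, collagens, integrins, YAP/TAZ targets, replication, mitosis, repair, p53 targets, interferon-stimulated genes, the unfolded protein response, NF-kB, hypoxia, cholesterol synthesis, oxidative phosphorylation, mitochondrial mRNAs, immediate early genes, glial markers, and blood, endothelial, epithelial, neuronal, oligodendrocyte and fibroblast markers. Lists were tested with camera (limma 3.58.1, two-sided) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 28 lists that had at least 5 tested members; 3 list members had no match in the tables. With a correlation estimated from the data, and with fry, no list passed in any contrast, and the p printed for an estimated correlation is unadjusted. Named genes are XRN2, then for each line and for the mean the 10 higher and 10 lower genes with the smallest p among those past the threshold that changed at least 1.5-fold with libraries wholly apart from the controls (for the mean, in the same direction in both lines and against mock). For the other contrasts they are the 5 higher and 5 lower with the smallest p, and up to 4 members of each list that was called or held at least 3 called genes. Genes with clone-like names were passed over, and a few genes that the rule names are not reported here.

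Replicates were compared before they were averaged. Chi-square statistics per gene were 1.72 to 26.0 in the 6 replicate pairs, highest in U251 mock and in LN229 control siRNA, so no pair differed by as little as sampling noise. Reads outside genes were taken as mapped reads minus gene reads and made up 1.14% to 1.89% of mapped reads; introns took 5.58% to 9.55% of gene reads. Mitochondrial genes took a larger share of exon reads in each XRN2 siRNA library than in the mock and control siRNA libraries of its line, with 2.99% and 3.21% against 2.69% to 2.92% in LN229 and 3.17% and 3.19% against 2.57% to 3.16% in U251.

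Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of at least 5 CPM in 2 libraries, a replicate block, fits on the compared line or groups alone, mock or mock plus control siRNA as the control, and each library left out in turn. Unique exon reads, limma-voom with sample weights, a fit without the 2 libraries that stand apart, and the gene lists for the difference between the lines were added after the data were seen. Matches of 7-base words to 3′ UTRs used the GENCODE annotation for 12827 genes, 90.1% of those tested. The edgeR calls and the camera lists of the knockdown contrasts were tested on simulated counts with known changes, and the 7-base search in LN229 on shuffled log2 fold changes. The edgeR test on the mean of both lines found 28, 38, 41 and 47 of 50 genes changed 1.5, 2, 3 and 4-fold with 5 false calls among 14009 genes. A list with a set shift was found in each of the 3 knockdown contrasts with 0 of 27 other lists called by camera. Simulated genes varied independently, with the same spread in all groups. False list calls from correlated genes or from a library that stands apart could therefore not arise there. In the sequenced libraries control siRNA against mock called 4 lists in LN229 and 12 in U251, with 0 genes called in either line. Software was R 4.3.3, the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.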

Results

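RNA from LN229 and U251, established human glioblastoma cell lines, was sequenced 72 hours after the cells were transfected with XRN2 siRNA, with control siRNA or without siRNA (mock). XRN2 encodes a nuclear 5′-to-3′ exoribonuclease known to degrade the RNA that is still being transcribed after cleavage at the poly(A) site. The 12 libraries form 6 groups of 2, and the design asks how the transcriptome of each line changes when XRN2 is depleted. Between 4846768 and 7469052 reads per library were assigned to exons, and 16660 to 18208 genes had at least 1 read. A count of 0 allows up to 3 reads, which correspond to 0.402 to 0.619 CPM (counts-per-million) across the libraries and cover counting error only. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

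The libraries separated by cell line first. The first principal component held 86.6% of the variance of log2 CPM and separated LN229 from U251, and the next 2 held 3.47% and 2.54%. In 2 libraries the values stood apart from those of the replicate. LN229 control siRNA replicate 1 had an intron share of 5.58% of gene reads against 8.78% in replicate 2, and its log2 difference from replicate 2 fell with exon length (Spearman −0.59 across 11589 genes, which are not independent replicates; −0.05 to 0.11 in the other 5 pairs). Its long transcripts were low, with ATM at 9.88 CPM against 34.9 and AHNAK at 495 against 1476. U251 mock replicate 2 held high levels of stress-response transcripts, among them DDIT3 at 403.5 CPM against 15.1 in replicate 1 and HSPA5, which encodes an endoplasmic reticulum chaperone, at 19522 against 1637.

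XRN2 itself was low in every XRN2 siRNA library. In LN229 its level was 29.6 ± 5.6 CPM (SD, n = 2) with XRN2 siRNA, 222 ± 29 with control siRNA and 232 ± 4.16 in mock, so that 13.3% of the control siRNA level remained. In U251 the levels were 28.6 ± 3.45, 139 ± 6.96 and 140.5 ± 3.56 CPM, and 20.5% remained. XRN2 (ENSG00000088930) lies on chromosome 20 from 21303304 to 21389827 on the plus strand, in GRCh38 coordinates. The log2 fold change against control siRNA was −2.90 (SE 0.17, adjusted p = 3.75e-06) in LN229 and −2.28 (SE 0.17, adjusted p = 6.50e-05) in U251 by edgeR's quasi-likelihood test. The knockdowns of the lines differed by −0.62 (SE 0.23), which did not pass the test of the difference (edgeR adjusted p = 0.722). Control siRNA and mock differed in XRN2 by −0.06 in LN229 and −0.01 in U251, less than the standard errors of 0.15 and 0.16. Reads in XRN2 introns did not follow the exon reads. As RPM (reads-per-million) of all gene reads, they were at 22.8 ± 1.43 with XRN2 siRNA, 15.8 ± 8.59 with control siRNA (9.74 in replicate 1 and 21.9 in replicate 2) and 22.8 ± 0.784 in mock in LN229, and at 10.9 ± 1.5, 13.2 ± 0.543 and 12.5 ± 0.946 in U251 (SD, n = 2).

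**Figure D1:**
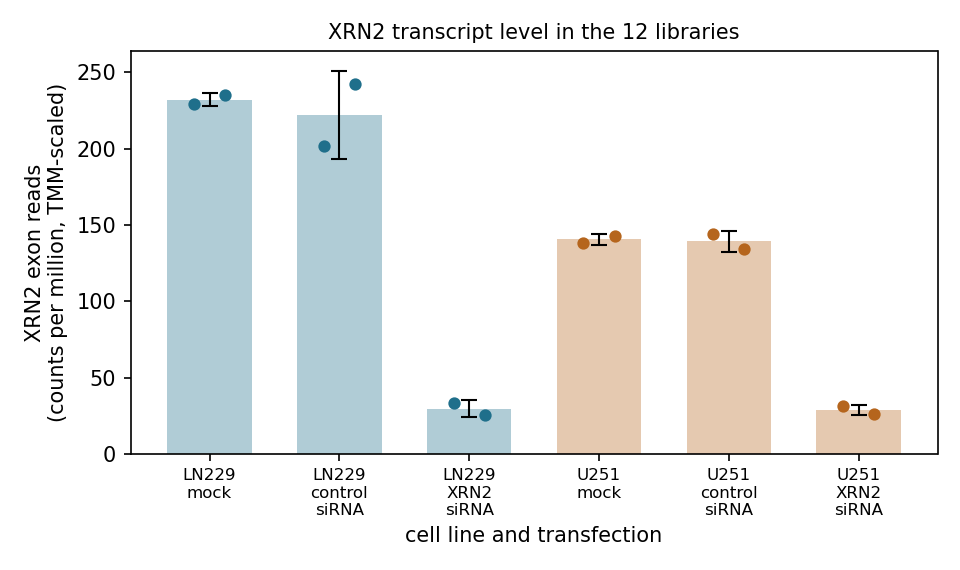
XRN2 exon reads in CPM, scaled by trimmed mean of M-values, for the 6 groups of 2 libraries; bars show group means, whiskers the SD and points the libraries. The 4 XRN2 siRNA libraries lie between 25.6 and 33.5, and the 8 other libraries between 134 and 243.

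In LN229, XRN2 siRNA lowered NEU1, GLB1 and the mitotic regulator CDC20 and raised P2RX7, TGFBR2 and PRKCD, among 450 genes. NEU1 (ENSG00000204386; chromosome 6, 31857659 to 31862906), the lysosomal sialidase, fell from 81.2 ± 5.79 to 25.9 ± 5.39 CPM (SD, n = 2), a log2 fold change of −1.64 (SE 0.17, adjusted p = 0.00179). P2RX7 (ENSG00000089041; chromosome 12, 121132819 to 121188032), an ATP-gated cation channel, rose from 28.1 ± 9.27 to 80.8 ± 4.82 CPM, a log2 fold change of 1.51 (SE 0.20, adjusted p = 0.00859). TGFBR2 (ENSG00000163513; chromosome 3, 30606502 to 30694142), the type II receptor for TGF-beta, rose from 141 ± 18.8 to 277 ± 39.1 CPM, a log2 fold change of 0.97 (SE 0.15, adjusted p = 0.0125). In all, 450 of 14232 genes passed edgeR's test at an adjusted p under 0.05, with 172 higher and 278 lower than with control siRNA, and 86 of the higher and 101 of the lower genes changed at least 2-fold. Without TMM factors, with library sizes still used, the split was 277 higher and 197 lower.

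Among the other lower genes with the smallest p in LN229, GLB1 (lysosomal beta-galactosidase) had a log2 fold change of −1.10 (SE 0.14), CTSB (the lysosomal protease cathepsin B) −1.05 (SE 0.15) and SUMF1 (the enzyme that activates sulfatases) −1.55 (SE 0.19). SCOC fell by 1.28 on the log2 scale, SPP1, which encodes the secreted glycoprotein osteopontin, by 0.97, LEPROT by 1.23 and MT2A, a metallothionein, by 1.43. Their adjusted p-values were between 0.00649 and 0.0125. Among the other 8 higher genes, DNHD1 had a log2 fold change of 1.95 (SE 0.23), CUBN, an endocytic receptor, 1.87 (SE 0.26), AATK, a kinase, 1.71 (SE 0.26) and PRKCD, protein kinase C delta, 1.29 (SE 0.19). PSMG3-AS1, FHDC1, SIPA1L2 and FAM114A1 rose by 1.42, 1.38, 1.22 and 0.94, with adjusted p-values of 0.00605 to 0.0125 for all 8. PSMG3-AS1 is antisense to PSMG3 by its name, though its annotated biotype is lincRNA. The library kit does not keep strand, so its reads cannot be told apart from those of PSMG3 wherever the genes overlap. The 3′ UTRs of NEU1, SCOC, GLB1, CTSB and SPP1 held at least 1 of 6 7-base words that marked lower genes in LN229, as did those of the higher genes P2RX7, TGFBR2 and FAM114A1, while SUMF1, LEPROT and MT2A held none. LEPROT overlaps LEPR, and MT2A has close paralogs, so their values are uncertain in the same way.

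Transcripts for cell division were lower as a group in LN229. All 39 tested genes of the mitosis and G2/M list lay below 0, with a median log2 fold change of −0.65. Of these, 15 fell past the threshold over all genes and 32 when adjusted over the list alone (camera adjusted p = 2.45e-17, and p = 0.0792 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell by 1.19 on the log2 scale (SE 0.18), its activator CDC20 by 1.05 (SE 0.18), the mitotic kinase PLK1 by 0.98 (SE 0.17) and cyclin B1 (CCNB1) by 0.88 (SE 0.16). In the list of DNA replication and G1/S all 41 genes lay below 0, with a median of −0.61. Of these 3, GINS2 at −0.99, POLE2 at −1.39 and LIG1 at −0.80, fell over all genes and 22 when adjusted over the list alone (camera adjusted p = 2.92e-12, and p = 0.169 with an estimated correlation). Of 39 DNA damage repair genes 1 fell, H2AFX at −1.14, and adjusted over the list alone 4 were lower and 1 higher. The list's median was −0.28 (camera adjusted p = 0.00827, and p = 0.386 with an estimated correlation). For XRN2 knockdown in LN229 the mitosis and replication lists passed with each library left out. The repair list's adjusted p was 0.588 without control siRNA replicate 2 and 0.360 without XRN2 siRNA replicate 2.

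The list of interferon-stimulated genes was the only list of 28 that was called higher in LN229. Its median log2 fold change was 0.31, with 34 of 39 genes above 0 (camera adjusted p = 2.06e-04, and p = 0.146 with an estimated correlation). DHX58, a cytoplasmic RNA sensor, rose by 1.23 (SE 0.29, adjusted p = 0.0388) and MX1, an antiviral GTPase, by 1.25 (SE 0.31, adjusted p = 0.0482), and 3 genes passed when adjusted over the list alone. The levels were low: DHX58 was at 4.07 ± 0.91 CPM with control siRNA and 9.73 ± 1.86 with XRN2 siRNA, and MX1 at 4.05 ± 0.256 and 9.65 ± 0.982 (SD, n = 2). IFIT3 had a log2 fold change of 0.65 (SE 0.19) and did not pass (adjusted p = 0.0703). Against mock DHX58 was at 0.93 (adjusted p = 0.102) and MX1 at 1.11 (0.0777).

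Genes of translation and respiration were lower with XRN2 siRNA than with control siRNA in LN229, in lists that also differed between the control siRNA replicates. All 42 cytosolic ribosomal protein genes lay below 0, with a median of −0.36 (camera adjusted p = 1.10e-06, and p = 0.352 with an estimated correlation). The same list was higher by 0.64 in control siRNA replicate 1 than in replicate 2. RPS2 was at −0.68 (SE 0.17, adjusted p = 0.0516), and no ribosomal protein gene passed by itself, over all genes or when adjusted over the list alone. Of 38 nuclear genes of oxidative phosphorylation, COX8A at −1.25 (SE 0.23) and NDUFA2 at −1.35 (SE 0.27), subunits of respiratory complexes, fell, and against mock they were at −0.89 (adjusted p = 0.0742) and −0.92 (0.108). Adjusted over the list alone 2 fell as well, and the list's median was −0.36 (camera adjusted p = 1.20e-05, and p = 0.319 with an estimated correlation). This list was 0.51 higher in control siRNA replicate 1. The 21 snoRNA host genes had a median of −0.37, with SNHG1 at −0.69 (SE 0.23) and none past the threshold either way (camera adjusted p = 0.00676, and p = 0.322 with an estimated correlation). They were 0.58 higher in that replicate. In XRN2 knockdown in LN229 without control siRNA replicate 1 these 3 lists had adjusted p-values of 0.766, 0.798 and 0.820, with the ribosomal list turned higher, and with mock as the control 0.944 (again higher), 0.944 and 0.316. The snoRNA host list also had 0.0737 without XRN2 siRNA replicate 2. The 38 ribosome biogenesis genes had a median of −0.29, with 11 lower when adjusted over the list alone and FBL, the box C/D snoRNA methyltransferase, at −0.68 (SE 0.19, adjusted p = 0.0624). The list was called (camera adjusted p = 9.70e-04, and p = 0.335 with an estimated correlation) and stayed under 0.05 without that library (0.0115) and against mock (0.0199). It was 0.17 higher in control siRNA replicate 1.

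Genes of motility and matrix moved in both directions in LN229. In the list of epithelial-mesenchymal transition, PLAUR, the urokinase receptor, fell by 1.17 on the log2 scale (SE 0.24, adjusted p = 0.0251) and ZEB2, a transcriptional repressor, rose by 0.90 (SE 0.20, adjusted p = 0.0325), and against mock they were at −1.001 (adjusted p = 0.0551) and 0.53 (0.189). In this list 6 genes were lower and 1 higher when adjusted over the list alone. The median of 34 genes was −0.18 (camera adjusted p = 0.0402, and p = 0.117 with an estimated correlation). Of 41 integrin and focal adhesion genes, ITGB1, the beta-1 integrin chain, fell by 1.42 (SE 0.24), FERMT2 (kindlin-2) by 0.84 and ITGA3 by 0.77, and ITGA2 rose by 0.85 (SE 0.20), with adjusted p-values of 0.0141 to 0.0426. ITGA2 was at 0.28 (SE 0.20, adjusted p = 0.547) against mock and did not pass without control siRNA replicate 1 (0.130). In all 4 were lower and 1 higher, 6 and 1 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.113). In XRN2 knockdown in LN229 the integrin list passed without control siRNA replicate 1 (0.00228) and against mock (0.00315). The transition list did not pass without control siRNA replicate 1 (0.0602) or 2 (0.170) or XRN2 siRNA replicate 2 (0.172). Of 35 collagen and matrix glycoprotein genes, COL16A1 rose by 0.67 and LAMC1, a laminin chain, by 0.75, while LUM (lumican) fell by 1.31 and THBS2 (thrombospondin 2) by 0.81. Adjusted over the list alone 4 were higher and 3 lower, and the list was not called (camera adjusted p = 0.116), except without control siRNA replicate 2 (0.00730). Of 23 matrix proteases and inhibitors 2 were lower, 4 when adjusted over the list alone (camera adjusted p = 0.124).

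Of the remaining lists 2 were called in LN229. Cholesterol biosynthesis (24 genes) had a median of −0.20 (camera adjusted p = 0.0271, and p = 0.203 with an estimated correlation). Immediate early genes (29) had a median of −0.30 (camera adjusted p = 0.0481, and p = 0.331 with an estimated correlation), with ETV4, an ETS transcription factor, the 1 member that fell, at −0.91 (SE 0.22). Neither passed in XRN2 knockdown in LN229 without control siRNA replicate 1 (0.0602 and 0.247), control siRNA replicate 2 (0.114 and 0.110) or XRN2 siRNA replicate 2 (0.0737 and 0.194). Of 34 hypoxia and glycolysis genes LDHA (lactate dehydrogenase A), PGAM1 and ADM fell, by 1.12, 1.19 and 1.06, and adjusted over the list alone 4 were lower and 3 higher (camera adjusted p = 0.301). The 35 genes of termination and 3′ end processing, the list closest to the known function of XRN2, had a median of 0.01 and were not called (camera adjusted p = 0.714). No call was made for p53 targets (0.687), the unfolded protein and ATF4 response (0.277), NF-kB and inflammatory cytokines (0.663), YAP/TAZ targets (0.812), replication-dependent histones (0.812), mitochondrially encoded mRNAs (0.737) or glial and neural stem markers (0.301), all camera adjusted p-values. Markers of other cell types were not called either, with camera adjusted p-values of 0.113 for endothelial, 0.0977 for epithelial, 0.165 for neuronal, 0.123 for oligodendrocyte and 0.711 for fibroblast and pericyte markers, and 3 blood cell markers were too few to test. In simulated counts for XRN2 knockdown in LN229 over 14009 genes the test found 8 of 50 genes changed 1.5-fold, 34 of 50 changed 2-fold and 42 of 50 changed 3-fold, with 11 false calls.

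The count in LN229 depended on single libraries. It was 68 without control siRNA replicate 1, 3296 without control siRNA replicate 2, 829 without XRN2 siRNA replicate 1 and 1, XRN2, without XRN2 siRNA replicate 2. Mock as the control gave 183 genes, in a comparison that shares the XRN2 siRNA libraries. Of these genes 135 were among the 450, and 449 of the 450 had the same direction against mock. The count also rested on pooling the spread of both lines. With the compared groups alone 4 genes passed in LN229, and with the LN229 libraries alone 1. In U251 the compared groups alone gave 497. Chi-square statistics per gene of these replicate pairs were 18.4 and 7.30 in LN229, and 2.48 and 1.72 in U251. A larger count in LN229 than in U251 thus does not show a larger response. Of 46 named genes called in LN229, 15 did not pass against mock: PLAUR, ZEB2, LAMC1, FERMT2, ITGA2, GINS2, POLE2, CCNB1, DHX58, MX1, PGAM1, ADM, COX8A, NDUFA2 and ETV4. Fold changes in LN229 rose with exon length (Spearman 0.36 across genes, and 0.01 without control siRNA replicate 1). The median exon length was 6959 bases among the higher genes, 3396 among the lower and 4876.5 among all tested.

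In U251, XRN2 was the 1 gene of 14232 that passed edgeR's test, while 553 genes had an unadjusted p under 0.05 and DESeq2 called 9. In simulated counts for XRN2 knockdown in U251 the same test found 29 of 50 genes changed 2-fold and 6 of 50 changed 1.5-fold over 14009 genes. Fitted on the libraries of the compared groups alone, 497 genes passed, 194 higher and 303 lower.

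Cell division genes were lower in U251 as a group. All 39 mitosis and G2/M genes lay below 0, with a median log2 fold change of −0.39 (camera adjusted p = 5.41e-18, and p = 0.0750 with an estimated correlation). CDC20 was at −0.55 (SE 0.18), the mitotic kinesin KIF2C at −0.63 (SE 0.18), the centromeric histone CENPA at −0.55 (SE 0.22) and the transcription factor FOXM1 at −0.55 (SE 0.22). None of these passed by itself in edgeR (adjusted p = 1), nor when adjusted over the list alone. In the list of DNA replication and G1/S 39 of 41 genes lay below 0 with a median of −0.26 (camera adjusted p = 8.79e-06, and p = 0.330 with an estimated correlation), and POLA2 was at −0.70 (SE 0.23). In XRN2 knockdown in U251 with mock as the control the replication list had an adjusted p of 0.981; it lay 0.50 lower in U251 mock replicate 2, the library that stands apart, than in replicate 1. Replication-dependent histones were higher, with a median of 0.48 and 10 of 13 genes above 0 (camera adjusted p = 0.00202, and p = 0.0319 with an estimated correlation). Of 33 listed histone genes 13 could be tested, and since the kit selects polyadenylated RNA their reads stand largely for polyadenylated transcripts. Whether histone mRNA without a poly(A) tail changed cannot be read from these libraries. HIST1H2BD was at 1.05 (SE 0.42), HIST1H2BK at 0.86 (SE 0.35), HIST1H1C at 0.60 (SE 0.21) and HIST1H2AC at 0.46 (SE 0.18), members of near-identical gene families for which the splitting of reads is uncertain. None of the 13 passed alone in edgeR, over all genes or when adjusted over the list alone, and without XRN2 siRNA replicate 2 the list did not pass (0.0562). The termination list was not called (camera adjusted p = 0.612). Leaving out control siRNA replicate 2 brought ribosome biogenesis (0.0111) and DNA damage repair (0.00331) under 0.05, as did leaving out XRN2 siRNA replicate 1 for the repair list (0.0341). The same held on leaving out control siRNA replicate 1 for the interferon list, lower (0.0153), and on leaving out XRN2 siRNA replicate 2 for the fibroblast and pericyte markers (0.00863).

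**Figure D2:**
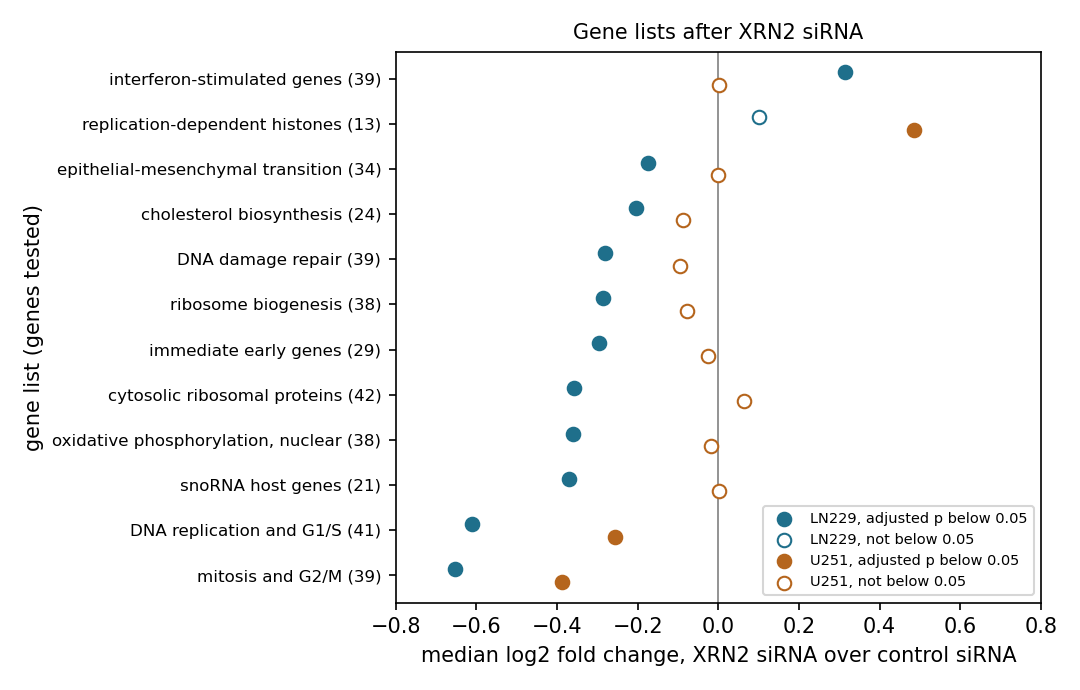
Median log2 fold change (XRN2 siRNA over control siRNA, n = 2 per group) of the 12 gene lists called in LN229 or U251, with the number of genes tested in brackets; filled points have a camera adjusted p under 0.05 at a preset correlation of 0.01, open points do not. Mitosis and replication lists are lower in both lines, at −0.65 and −0.61 in LN229 and −0.39 and −0.26 in U251; with an estimated correlation no list passes.

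Averaged over both lines, 173 genes passed, 63 higher and 110 lower, of which 22 and 11 changed at least 2-fold (edgeR, 14232 genes tested). SPP1 (ENSG00000118785; chromosome 4, 87975650 to 87983426) was at 132.5 ± 0.534 CPM with control siRNA and 67.6 ± 6.88 with XRN2 siRNA in LN229, and at 118 ± 15.6 and 68.9 ± 2.39 in U251 (SD, n = 2), a mean log2 fold change of −0.87 (SE 0.10, adjusted p = 0.00497). NRGN (ENSG00000154146; chromosome 11, 124739846 to 124747210), a calmodulin-binding protein, had a mean of −1.38 (SE 0.17, adjusted p = 0.00662), with −1.51 in LN229 and −1.25 in U251, where it did not pass alone (adjusted p = 0.197). Against mock NRGN was at −1.02 in LN229 (edgeR adjusted p = 0.0568) and −0.77 in U251 (0.368). It was 0.48 higher with control siRNA than in mock in each line. PSMG3-AS1 was at 22.6 ± 0.0174 CPM with control siRNA and 60.5 ± 14.9 with XRN2 siRNA in LN229, and at 5.67 ± 0.541 and 11.4 ± 0.358 in U251, a mean of 1.21 (SE 0.15, adjusted p = 0.00714). SERPINA5, a serine protease inhibitor of the protein C system, had a mean of 1.18 (SE 0.17, adjusted p = 0.0142), with 0.48 in LN229 and 1.87 in U251, neither past the threshold alone (adjusted p = 0.171 and 0.0589).

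The other lower genes with the smallest p in the mean were NEU1 at −1.04 (SE 0.12), SCOC at −0.84, TFPI, an inhibitor of the coagulation cascade, at −0.91 (SE 0.13), GLB1 at −0.71, SUMF1 at −0.85 and LEPROT at −0.87, with adjusted p-values of 0.00422 to 0.0189. The other higher genes were DNHD1 at 1.26 (SE 0.17), the transcribed pseudogene FER1L4 at 1.39, ALDH3B1 at 0.93, the natriuretic peptide receptor NPR2 at 0.87, SEL1L3 at 1.02, XKR4 at 0.77, LCTL at 0.65 and FAM114A1 at 0.59, with adjusted p-values of 0.0108 to 0.0202. In U251 alone NEU1, SUMF1 and SEL1L3 were at −0.44 (SE 0.16), −0.15 (SE 0.17) and 0.26 (SE 0.18), none past the threshold.

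Of the lists, mitosis and G2/M had 11 genes that fell over all genes and 37 of 39 when adjusted over the list alone, with a median of −0.51 (camera adjusted p = 1.68e-22, and p = 0.0527 with an estimated correlation). CDC20, UBE2C and KIF2C were at −0.80, −0.81 and −0.79 (adjusted p = 0.0202 each) and CCNB1 at −0.64 (adjusted p = 0.0224). In DNA replication and G1/S POLA2 fell by 0.71 (SE 0.15, adjusted p = 0.0429) and 21 of 41 genes were lower when adjusted over the list alone, with a median of −0.40 (camera adjusted p = 2.23e-13, and p = 0.153 with an estimated correlation). H2AFX fell by 0.77 and DHX58 rose by 0.90, the 1 called member each of the repair and interferon lists. The repair list was lower, with 3 genes adjusted over the list alone (camera adjusted p = 0.00339, and p = 0.339 with an estimated correlation). The interferon list was higher, with 1 gene adjusted over the list alone (camera adjusted p = 0.0203, and p = 0.301 with an estimated correlation). In the transition list PLAUR at −0.94 and NT5E, the ecto-5′-nucleotidase CD73, at −0.999 fell, with 3 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0282, and p = 0.0965 with an estimated correlation). In the integrin list ITGB1 at −0.93, FERMT2 at −0.57 and ITGB5 at −0.41 fell, with 7 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.0309, and p = 0.287 with an estimated correlation). COX8A and NDUFA2 fell by 0.81 and 0.89.

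The other lists called in the mean were oxidative phosphorylation (camera adjusted p = 2.43e-04, and p = 0.376 with an estimated correlation), ribosome biogenesis (3.97e-04, and p = 0.299), cytosolic ribosomal proteins (0.00299, and p = 0.534), snoRNA host genes (0.0288, and p = 0.418), cholesterol biosynthesis (0.0282, and p = 0.205) and immediate early genes (0.0288, and p = 0.297), with medians between −0.20 and −0.14. None of these 6 passed in U251, where 38 of 42 ribosomal protein genes lay above 0 (median 0.063) and snoRNA host genes 11 of 21 (0.0019). For XRN2 knockdown, mean of both lines, without LN229 control siRNA replicate 1, which was 0.64 higher in ribosomal protein, 0.58 higher in snoRNA host and 0.51 higher in respiratory genes than replicate 2, those lists had adjusted p-values of 0.199 (turned higher), 0.785 and 0.467, and against mock the ribosomal (higher) and respiratory lists had 0.984 each. The snoRNA host list had 0.133 without LN229 XRN2 siRNA replicate 2 and 0.0503 without U251 XRN2 siRNA replicate 2. The interferon list had 0.0574 without that library, 0.0617 without LN229 control siRNA replicate 2, 0.133 without LN229 XRN2 siRNA replicate 2 and 0.187 without U251 control siRNA replicate 1. The repair list had 0.376 without LN229 control siRNA replicate 2 and 0.122 without LN229 XRN2 siRNA replicate 2, and the integrin list 0.494 and 0.0868, with 0.0507 without U251 control siRNA replicate 1 and 0.0547 without U251 XRN2 siRNA replicate 2. Without LN229 control siRNA replicate 1, control siRNA replicate 2 or XRN2 siRNA replicate 2 the transition list had 0.0574, 0.0963 and 0.0868, cholesterol biosynthesis 0.0574, 0.0714 and 0.0827, and immediate early genes 0.164, 0.0617 and 0.133. Cholesterol biosynthesis also had 0.0590 without U251 XRN2 siRNA replicate 1, and immediate early genes 0.0601 without that library and 0.108 without U251 control siRNA replicate 2. The mitosis, replication and ribosome biogenesis lists passed with each library left out.

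The count of 173 in the mean was 647 without the 2 libraries that stand apart. It was 76 without LN229 control siRNA replicate 1, 2370 without LN229 control siRNA replicate 2, 587 and 21 without LN229 XRN2 siRNA replicate 1 and 2, 4 and 1 without U251 control siRNA replicate 1 and 2, and 8 and 1 without U251 XRN2 siRNA replicate 1 and 2.

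The genes that changed in LN229 leaned the same way in U251. Of 277 genes lower in LN229 besides XRN2, 244 were below 0 in U251, with a median log2 fold change of −0.25, outside the range of −0.05 to 0.03 that 10000 random lists of that size matched on expression gave. Of 172 genes higher in LN229, 121 were above 0 in U251, with a median of 0.18 against −0.07 to 0.07 for random lists. Over all genes 50.5% lay above 0 in U251. The random lists were drawn gene by gene, so their range does not allow for genes that vary together. Over 14231 genes the fold changes of the lines had a Pearson correlation of 0.16 and a Spearman correlation of 0.32, across genes, which are not independent replicates. The lines had separate control libraries, so no shared control enters these values.

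**Figure D3:**
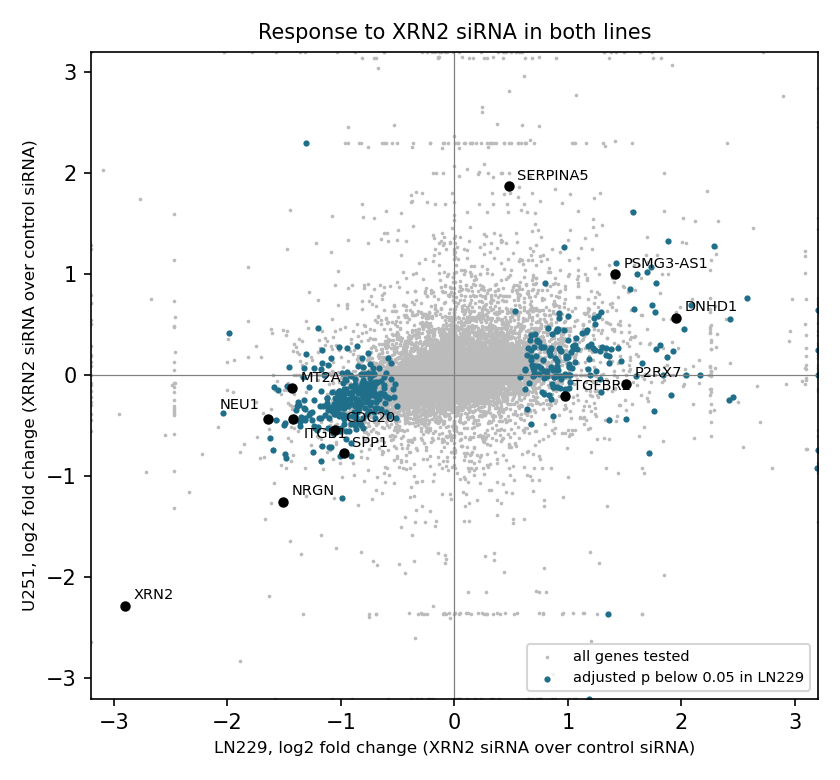
Log2 fold change (XRN2 siRNA over control siRNA) in U251 against that in LN229 for the 14232 genes tested; blue points passed edgeR's test in LN229, black points are labelled genes, and 140 genes beyond the axis limit of 3.2 are drawn at it. XRN2, NRGN, SPP1 and NEU1 lie below 0 in both lines, and P2RX7 and TGFBR2 rise in LN229 with U251 values of −0.09 and −0.21 that did not pass.

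The difference of XRN2 knockdown between lines, LN229 minus U251, was tested in the same model. No gene passed in edgeR, where the smallest adjusted p was 0.411, 945 genes had an unadjusted p under 0.05 and DESeq2 called 15. The DESeq2 genes included TGFBR2, with a difference (LN229 minus U251) of 1.21 (SE 0.26), COL11A1 at 1.16 (SE 0.23), PRKCD at 1.49 (SE 0.35), NEU1 at −1.18 (SE 0.26), SUMF1 at −1.38 (SE 0.32) and MT2A at −1.28 (SE 0.31). They were picked out after their values were seen. Leaving out LN229 control siRNA replicate 2 gave 1115 genes in edgeR.

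Control siRNA against mock measures the effect of adding control siRNA to the transfection. In LN229 no gene passed edgeR's test, with 647 at an unadjusted p under 0.05 and 1 called by DESeq2. Without control siRNA replicate 2, which leaves replicate 1 alone in its group, edgeR called 1913. Cytosolic ribosomal protein genes lay above 0 in 42 of 42 cases with a median of 0.36 (camera adjusted p = 1.83e-13, and p = 0.188 with an estimated correlation). So did oxidative phosphorylation in 37 of 38 with 0.35 (camera adjusted p = 5.79e-11, and p = 0.166 with an estimated correlation). NF-kB and inflammatory cytokines lay above 0 in 21 of 23 with 0.30 (camera adjusted p = 0.00433, and p = 0.00829 with an estimated correlation) and snoRNA host genes in 20 of 21 with 0.25 (camera adjusted p = 0.0139, and p = 0.329). In control siRNA against mock in LN229 without control siRNA replicate 1, which was higher than replicate 2 by 0.64, 0.51, 0.10 and 0.58 in these lists, their adjusted p-values were 0.906, 0.553, 0.237 and 0.728. The ribosomal and snoRNA host lists turned lower. The snoRNA host list had 0.0867 without mock replicate 2, and NF-kB 0.0775 without control siRNA replicate 2. Of list members, CXCL1, a neutrophil chemokine, was at 1.16 (SE 0.34) and UQCRQ at 0.55 (SE 0.19), neither past the threshold (edgeR adjusted p = 0.802).

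In U251 the same comparison gave no gene in edgeR, with 682 at an unadjusted p under 0.05 and 0 called by DESeq2. Without mock replicate 1, which leaves replicate 2 alone in its group, edgeR called 475. The unfolded protein and ATF4 response list lay at a median of −1.52 with 25 of 31 genes lower when adjusted over the list alone (camera adjusted p = 1.93e-15, and p = 0.0922 with an estimated correlation). It was 2.22 higher in mock replicate 2 than in replicate 1. DDIT3 was at −3.88 (SE 1.22) and HERPUD1 at −3.48 (SE 1.08), and neither passed (edgeR adjusted p = 0.973). Also lower were ribosome biogenesis (median −0.19, camera adjusted p = 1.14e-06, and p = 0.180 with an estimated correlation), snoRNA host genes (−0.21, 1.575e-04, and p = 0.2), immediate early genes (−0.31, 7.20e-04, and p = 0.139). Likewise lower were YAP/TAZ targets (−0.17, 0.00221, and p = 0.243) and NF-kB and inflammatory cytokines (−0.24, 0.0190, and p = 0.0243 with an estimated correlation). Higher were replication (0.29, 2.97e-05, and p = 0.360 with an estimated correlation), hypoxia and glycolysis (0.22, 5.56e-05, and p = 0.181), mitochondrially encoded mRNAs (0.15, 0.00690, and p = 0.250), interferon-stimulated genes (0.32, 0.0108, and p = 0.282), collagens (0.14, 0.0437, and p = 0.363) and mitosis (0.11, 0.0437, and p = 0.591). Without mock replicate 2 none of the 12 lists passed control siRNA against mock in U251, with adjusted p-values of 0.973. Collagens also had 0.0814 without mock replicate 1 and 0.547 without control siRNA replicate 2, interferon-stimulated genes 0.837 without control siRNA replicate 2, and mitosis 0.839 and NF-kB 0.0638 without control siRNA replicate 1.

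Between the mock-treated lines, 7820 genes differed, with 3987 higher and 3833 lower in LN229 mock than in U251 mock (edgeR). ERBB3, a receptor tyrosine kinase, was at 536 ± 10.98 CPM in LN229 and 0.529 ± 0.0630 in U251 (SD, n = 2), a log2 fold change of 9.94 (SE 0.27, adjusted p = 1.01e-10). SOX10, a transcription factor of neural crest and oligodendrocyte lineages, was at 742 ± 45.1 CPM in LN229 with no read in the U251 mock libraries, where 3 reads would be 0.451 to 0.536 CPM. EXTL1, NFATC2 and the cancer-testis antigen MAGEA3, which has near-identical family members, were higher in LN229 by 6.93, 6.83 and 7.002. THY1, a cell surface glycoprotein of mesenchymal cells, was at 804 ± 238 CPM in U251 and 0.988 ± 0.0390 in LN229 (log2 fold change −9.64, SE 0.29), and LAYN and COL14A1 were lower in LN229 at −8.44 and −7.59. PIPOX was at 201 ± 16.1 CPM in U251 with no read in LN229 mock, where 3 reads would be 0.402 to 0.509 CPM. The lines were grown in different media with 5% and 10% serum, so line and medium cannot be separated here.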

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

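The tests of transcript length and of the single control siRNA library, the permutation of the share outside genes, and the gene lists on the difference between the lines were chosen only after the results were seen.

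Camera at the preset correlation called 8 gene lists on the difference of the XRN2 siRNA response between the lines, LN229 minus U251. With an estimated correlation and with fry 0 lists were called, and 0 genes passed edgeR's test of the difference. A differing response is thus not shown, and the list of epithelial markers held only 8 tested genes. Interferon-stimulated genes (adjusted p = 1.90e-05, and p = 0.107 with an estimated correlation) and collagens and matrix glycoproteins (0.0327, and p = 0.319) were higher in LN229, with medians of 0.39 and 0.28. Cytosolic ribosomal proteins (4.40e-08, and p = 0.294 with an estimated correlation), replication (1.67e-05, and p = 0.341), mitosis (1.90e-05, and p = 0.302), oxidative phosphorylation (1.78e-04, and p = 0.381), epithelial markers (0.00702, and p = 0.0188) and snoRNA host genes (0.0105, and p = 0.341) were lower, with medians of −0.43, −0.40, −0.33, −0.28, −0.56 and −0.36. In difference of XRN2 knockdown between lines without LN229 control siRNA replicate 1 the ribosomal, respiratory, snoRNA host, collagen and epithelial lists had 0.545, 0.833, 0.820, 0.704 and 0.156. Without LN229 XRN2 siRNA replicate 2 mitosis, replication and snoRNA host genes had 0.261, 0.544 and 0.139. The collagen list also had 0.179 without LN229 XRN2 siRNA replicate 1, 0.192 without U251 control siRNA replicate 2 and 0.0668 without U251 XRN2 siRNA replicate 2, and the epithelial list 0.1, 0.0991 and 0.0539, with 0.0594 without LN229 control siRNA replicate 2. The interferon list passed with each library left out.

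Of 124 named genes, 12 had every XRN2 siRNA library on one side of every control siRNA library in LN229 and on the other side in U251, of which 11 are given here. With 2 libraries per group such separation also arises readily by chance, and some of the named genes were picked for it. The share over all genes was not counted, so the number is no evidence of opposite responses. LN229 minus U251 was 1.18 for TGFBR2, 2.48 for AATK, 0.94 for IFIT3, 0.76 for IFI35, 1.22 for COL1A1 and 0.58 for COL5A2. It was −0.66 for RPS20, −0.59 for UQCRQ, −0.76 for HIST1H1C, −0.77 for HIST1H2AC and −2.27 for KRT15. In U251 AATK was at 0.423 CPM with control siRNA and 0.233 with XRN2 siRNA, near or under the level of 3 reads, so its direction there cannot be read. Nor can that of KRT15 in LN229 (−0.94, SE 0.89), at 1.21 and 2.53 CPM with control siRNA, 1.09 and 0.877 with XRN2 siRNA and 1.12 and 1.14 in mock. Against mock the LN229 changes of RPS20, UQCRQ, COL1A1, HIST1H1C and HIST1H2AC were −0.14, 0.07, 0.046, −0.072 and −0.069, where against control siRNA they were −0.60, −0.48, 0.43, −0.16 and −0.31. In U251 IFI35 was at −0.036 against mock and −0.42 against control siRNA, so for these 6 the direction in that line rests largely on the control siRNA libraries. None passed edgeR's test of the difference, with adjusted p-values of 0.411 to 0.747; over all genes 0 passed, 945 had an unadjusted p under 0.05 and DESeq2 called 15.

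The share of mapped reads outside genes, which enters no comparison of the report, was higher with XRN2 siRNA than in mock and control siRNA libraries, by 0.209 percentage points in LN229 (1.74% to 1.89% against 1.43% to 1.70%) and 0.213 in U251 (1.43% to 1.49% against 1.14% to 1.34%). An exact two-sided permutation within lines gave p = 0.00444 over 225 arrangements, and p = 0.0556 over 36 against control siRNA alone, each the smallest it can give. Genomic DNA is argued against, since it would raise intron reads of 1731 silent genes by 134 RPM in LN229 and 136.5 in U251, and they were higher by 11.5 ± 5.94 (SE) and 5.21 ± 2.42. Genes within 5 kb downstream of an expressed gene, 1220 in all, had a mean log2 fold change of 0.0143 in LN229 (percentile 24.7 of random lists) and 0.0652 in U251 (percentile 96.9), with U251 close to the upper bound of 0.0666. Whether so small a rise in reads outside genes could move these means was not checked. The values thus do not decide whether transcription runs into the next gene. Where these reads lie was not analysed here, so unprocessed RNA past poly(A) sites, which loss of XRN2 might leave, stays open as an untested hypothesis.

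The calls in LN229 rest partly on control siRNA replicate 1. Its difference from replicate 2 fell with exon length (Spearman −0.59 across genes; −0.05 to 0.11 in the other pairs), which is consistent with a loss of long transcripts in that library, and the ribosomal, respiratory and snoRNA host lists lost their call without it. This library alone does not account for all calls, since mock as the control, which shares the XRN2 siRNA libraries, gave 183 genes. An effect of XRN2 loss on the other genes stays open.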

How the results depend on the processing

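Unique exon reads, limma-voom with sample weights, the fit without the 2 libraries that stand apart and the lists on the difference between lines were chosen after the results were seen; all other settings were planned. No named gene that passed the test changed direction. The ribosomal protein list turned, without passing, in XRN2 knockdown in LN229 and in the mean, both against mock and without LN229 control siRNA replicate 1, and it and the snoRNA host list turned in control siRNA against mock in LN229 without that library. The cause of each change below was not tested, except that a left-out library leaves a group of 1, assumed to vary like the other groups. For XRN2 knockdown in LN229 (450 genes) DESeq2 gave 773, no filter 1550, the line's libraries only 1, the compared groups only 4, mock as the control 183, mock and control siRNA together 817, voom with weights 10, and leaving out 1 library 1 to 3296. For XRN2 knockdown in U251 (1 gene) DESeq2 gave 9, no filter 69, the line only 7, the compared groups only 497, mock 7, both controls 10, unique reads 4, voom with weights 143, without the 2 libraries 22, and leaving out 1 library 1 each. For XRN2 knockdown, mean of both lines (173) DESeq2 gave 471, no filter 1035, the compared groups only 16, both controls 590, without the 2 libraries 647, and leaving out 1 library 1 to 2370. For difference of XRN2 knockdown between lines (0) DESeq2 gave 15, no filter 144, and leaving out 1 library 0 to 1115. For control siRNA against mock in LN229 (0) DESeq2 gave 1, no filter 70, and leaving out 1 library 0 to 1913. For control siRNA against mock in U251 (0) no filter gave 247, the replicate block 1, and leaving out 1 library 0 to 475. LN229 against U251 in mock (7820) gave 6060 to 7194 with 1 library left out. Of the gene lists, an estimated correlation and fry left 0 called in every contrast. Gene lists, XRN2 knockdown in LN229 (11) were 6 to 11 with 1 library left out. Gene lists, XRN2 knockdown in U251 (3) were 8 with mock, 6 without the 2 libraries and 3 to 5 with 1 left out. Gene lists, XRN2 knockdown, mean of both lines (12) were 6 without the 2 libraries and 5 to 13 with 1 left out. Gene lists, difference of XRN2 knockdown between lines (8) were 4 to 10. Gene lists, control siRNA against mock in LN229 (4) were 0 without the 2 libraries and 0 to 4 with 1 left out, and gene lists, control siRNA against mock in U251 (12) were 0 and 0 to 12. XRN2 itself, XRN2 knockdown in LN229, stayed between −3.12 and −2.73 with 1 library left out and, XRN2, XRN2 knockdown in U251, between −2.41 and −2.17. Of 46 named genes called in LN229, 31 passed against mock, 41 of the 42 with an adjusted p in DESeq2, 22 without control siRNA replicate 1 and 1 without XRN2 siRNA replicate 2. The replicate numbers do not pair the samples (correlations of −0.04 to 0.06 in 6 pairs over 11589 genes), and the block changed no other call past 1.5 times. A similar count need not hold the same genes. In XRN2 knockdown in LN229 the block called 573, of which 413 were among the 450. A pseudocount setting applies to no count test and was not run. In simulated counts 1.5-fold changes were mostly missed within a line (8 of 50 in LN229, 6 of 50 in U251), and 28 of 50 were found in the mean of both lines.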

Other observations

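The named U251 genes, the list of lysosomal genes, the tests of ATCATGT and its reordered words, and the counts of 8-base words and of genes with seed matches were chosen only after results were seen; the splits and the 7-base search were not, but the splits with 2 libraries of each line per group were counted later.

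In U251, COL14A1, MMP7, KRT15 and EHF were higher with XRN2 siRNA when the compared groups were fitted alone, where 497 genes passed edgeR's test (194 higher, 303 lower) against 1 in the fit of all groups. COL14A1, a fibril-associated collagen, was at 469 and 535 CPM with control siRNA and 967 and 1099 with XRN2 siRNA (log2 fold change 1.04, SE 0.07). MMP7, the matrix protease matrilysin, was at 18.3 and 23.6 against 58.4 and 67.5 (1.59, SE 0.12), the keratin KRT15 at 55.9 and 62.5 against 132 and 167 (1.33, SE 0.11) and the epithelial transcription factor EHF at 39.6 and 43.7 against 96.3 and 117 (1.35, SE 0.10). IGFBP3 was higher by 1.04, and CTGF, a YAP/TAZ target, was at −0.63 (SE 0.06). Without the 2 libraries that stand apart 22 genes passed, XRN2, COL14A1, MMP7, KRT15 and EHF among them but not IGFBP3 or CTGF. These genes were chosen after their values were seen.

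NEU1, GLB1 and CTSB were among the lower genes with the smallest p in LN229, yet a list of 58 lysosomal genes, written after that was seen, was not lower as a group. Of 57 tested, 8 fell and 1 rose in LN229 with a median of 0.02 (camera p = 0.318 at the preset correlation), and in U251 camera gave p = 0.409.

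Of 34 splits fitted to the 8 XRN2 siRNA and control siRNA libraries with line as a term, 1, the real one, gave as many genes in edgeR as it did, 13, and the highest other gave 0. This fit left out mock and took a single effect for both lines, unlike the fit that gave 173. XRN2 was low in every XRN2 siRNA library, which favoured the real split in advance. In the other splits the XRN2 siRNA effect adds to the spread within groups, so the comparison is uneven. Only 18 of the splits keep 2 libraries of each line in each group, the real one included, and these are too few for a share under 5%.

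Genes lower with XRN2 siRNA could be targets of the siRNA through short 3′ UTR matches, which was tested over 16378 7-base words in 12827 genes. In LN229 16 words passed, lowest ATCATGT (t = −8.15) and TCATGTA (−7.52), and in U251 1 other word passed, so 0 passed in both lines, and control siRNA against mock gave 0 and 0. That counts against one seed strong enough to pass in both lines and leaves a weaker one open, since in U251 ATCATGT had t = −3.41 (rank 18) and 439 genes with ATCATGTA had a mean of −0.0647, below the lowest of 1000 matched lists (−0.0327), while CTTGTGCA (0.0027) and GACTATCA (−0.0610, lowest −0.0667) lay within their ranges. At least 1 of the 6 lowest words stood in 128 of 276 genes lower in LN229 (46.4%, matched genes 25.3%). In the mean of both lines it was 59 of 108 lower genes (54.6%, matched genes 28.4%). Of the higher genes it was 59 of 158 in LN229 (37.3%, matched genes 40.7%) and 22 of 55 in the mean (40%, matched genes 39.3%). In LN229 genes with ATCATGTA, CTTGTGCA and GACTATCA had means of −0.0656, −0.0876 and −0.0763. Each lay below the lowest of its matched lists (−0.0089, −0.0196 and −0.0604). In control siRNA against mock they lay within their ranges in both lines. The words were picked on LN229 values, so none of these shares and LN229 means is independent evidence. Of 402 reordered words without overlap the lowest t was −3.83, short of the LN229 threshold of −4.44, which argues against base composition alone. ATCATGT was picked as the lowest of all words, so its gap to the reordered words is partly due to the picking. The XRN2 transcript holds ATCATGT, CTTGTGC and TTGTGCA, as the seed of an XRN2 siRNA would need. TCATGTA, TTGTGCA and ACTATCA are ATCATGT, CTTGTGC and GACTATC shifted by 1 base to end in A. The transcript lacks TCATGTA, ACTATCA and GACTATC, but holds the reverse complements of GACTATC, CTTGTGC and TTGTGCA. Which siRNA strand would act was not tested. The transcript holds 17.5% of all words searched. Against mock in LN229, with the same XRN2 siRNA libraries, ATCATGT again had the lowest t (−9.06). The siRNA sequences are not given in the sources used here. SCOC, GLB1, CTSB, TFPI, NEU1 and SPP1 hold at least 1 of the 6 lowest words, as do the higher P2RX7, TGFBR2, FAM114A1, LCTL and XKR4. SUMF1, LEPROT, MT2A and NRGN do not. A few named genes cannot decide the question, so a seed effect stays open in both lines.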
